A study of Mus musculus with 16 samples.

How the data were processed

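The series holds 16 samples from the skin of female Balb/c mice, which are the 2 colour channels of 8 Agilent arrays. Mice received 100 µl of bleomycin at 1 mg/ml (BLM) or phosphate-buffered saline (PBS) under the skin of the back daily for 28 days, per the labels. Bleomycin injection is a mouse model of scleroderma. RNA carrying N6-methyladenosine (m6A), a methyl mark on adenosine in RNA, was pulled down with an m6A antibody. The immunoprecipitated RNA (IP) was labelled with Cy5 and the supernatant RNA left behind (Sup) with Cy3, and both were hybridised to 1 array, per the labels. Groups and replicate numbers come from the sample titles. A free-text field of the labels speaks of untreated embryonic stem cells, which contradicts the titles, the tissue field, the treatment field and the protocol, and it was not used. The labels call the 4 arrays of a group biological replicates and describe 16 mice in all, without saying which mice each array holds, so p-values measure the spread between arrays.

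The deposited scanner files hold spot intensities, and the IP file and the Sup file of each of the 8 arrays were the same bytes, so the red columns were read for IP and the green columns for Sup. Per the file headers, Agilent Feature Extraction 11.0.1.1 made the processed signal, an intensity with the background subtracted and the 2 dyes brought together within the array by a linear and a lowess step. That step sets the typical IP/Sup ratio of every array near 1. The deposited value table is on a log2 scale, and each of its columns equalled log2 of the processed signal minus 1 constant per channel, with a spread of 0. The origin of the constants is unknown. Column medians of that table ranged from -1.98 to -1.10 in the IP channels and from -0.85 to -0.40 in the Sup channels. Its 53157 rows were the array-design probes that were well above background in Cy5 on at least 4 of the 8 arrays, as tested on the flags of the scanner files. The submitters' processing notes name limma and no version.

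Each array had 62976 spots and 60641 array-design probes with 1 spot each. The probe names fall into 3 classes by their first letters, with 48057, 8497 and 4087 probes. The files used here do not pair these probes with genes, and the gene tables given matched none of them, so the 40 gene lists fixed in advance were not run and genes of interest could not be looked up. Control spots and spots flagged as outliers, between 0 and 41 per channel, were left out, and no spot was saturated. For arrays, the number of arrays limits the precision. As a measure of technical noise, 50 replicated probes had 10 spots each, and the median SD between spots was 0.068 log2 units in IP and 0.055 in Sup.

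All fits used limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend on mean signal), two-sided, with Benjamini-Hochberg adjustment at 0.05. The m6A ratio was log2(IP/Sup) of the processed signals, with each array centred on its median, over probes well above background in both channels on at least 4 of the 8 arrays. Expression was log2(IP + Sup), quantile-normalized over arrays, over probes well above background in either channel on at least 4 arrays. The dye step brings the IP and Sup channels of an array to a like level. The sum therefore does not weigh them by their share of the RNA, and a change in IP alone can move it. The IP and the Sup signal were also fitted alone on the log2 scale after quantile normalization. The median ratio of each array before centring was compared by an exact permutation test over 70 label assignments. A probe not well above background on any array of a group has only a bound there. Its fold is the mean of the bright group against the mean, per array of the dim group, of the higher of the probe's own signal and the lowest signal among probes well above background. Some probes above that lowest signal were still not well above background, so the bound is approximate.

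The rule for named items asked for the largest rises and falls past the threshold with groups that do not overlap and with a gene symbol. As no symbol was available, at most 2 probe IDs that rose and 2 that fell are printed by that rule. The control probes for Gapdh and Pgk1, 10 spots each, are the only probes with a mouse gene in their name. They were chosen outside the rule, after the files were seen, and their log2 total was set against the 75th percentile of the array. The suffixes 3 and 5 of their names are read as the 3′ and 5′ ends of the transcript.

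The arrays were scanned in 4 sessions. The first held BLM replicate 1, the second BLM replicates 2 and 4, the third BLM replicate 3 with PBS replicates 2, 3 and 4, and the fourth PBS replicate 1. Tests, thresholds and most alternatives were fixed before the data were examined. The alternatives were normexp background correction (offset 50, on median signals because the files used here hold no mean signal), other filters on dim probes, the value table, scaling to probes whose names point to spike-ins, the replicate number or the scan as a block, array weights (statmod 1.5.0), no variance trend, other thresholds, other normalizations, and leaving out each array. The labels say that spike-in RNA was added in equal amounts to both fractions, but the files do not say which probes measure it. The scaling used 48 of 102 probes that share a spike-in-like name and were well above background in all 16 channels, and it is a candidate only.

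The fits were tested on simulated data built from the real means and spreads, with 200 changed probes. For the m6A ratio over 51121 probes, 7% of changes of 1 log2 unit and 55% of changes of 2 log2 units were recovered. For expression over 54823 probes the shares were 16% and 58%, for IP over 53081 probes 7% and 62%, and for Sup over 52165 probes 8% and 57%. No recovered change had the wrong sign. False calls were 4 of 66 calls for the ratio, 4 of 78 for expression, 4 of 73 for IP and 10 of 75 for Sup. The real arrays also differ in ways that move many probes together. A split of them other than BLM against PBS called 15175 probes for expression. The simulated shares do not cover such differences.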

Results

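The data set measured RNA abundance and m6A methylation in mouse skin after daily injections of bleomycin or saline, with 4 BLM and 4 PBS arrays that each carried an IP and a Sup channel. Between 80.9% and 92.9% of the 60641 probes were well above background in the IP channels, and between 69.6% and 90.3% in the Sup channels. The comparisons ask which transcripts changed in abundance and which changed in their m6A ratio in this scleroderma model.

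The sum of IP and Sup, read as total abundance, rose at 658 probes and fell at 437 in BLM skin. These were among 54939 probes tested by limma, with 3781 higher and 4037 lower at an unadjusted p under 0.05. By fitted difference the first among the rises was probe ASMM10EP3A101423073, whose log2 signal was 13.01 ± 0.52 (SD, n = 4) in BLM and 6.02 ± 0.44 (SD, n = 4) in PBS, a 127-fold difference (log2 6.99, SE 0.30, limma adjusted p = 3.5e-05). Probe ASMM10EP3A100006930 rose 103-fold, from 6.81 ± 0.73 to 13.49 ± 0.35 (SD, n = 4 per group, limma adjusted p = 6.3e-05). With normexp background correction, which also used median signals and an offset, the differences of these 2 probes were 4.10 and 4.47 log2 units. The size and order of the rises therefore depend on the signal and the background correction used. By fitted difference the first among the falls was probe ASMM10EP3A118338059, 16.1-fold, from 15.45 ± 0.62 in PBS to 11.44 ± 0.70 in BLM (SD, n = 4 per group, limma adjusted p = 0.0017). In each of these 3 probes all 4 BLM arrays lay on 1 side of all 4 PBS arrays. Large changes were mostly rises, since 88 probes rose and 18 fell by over 8-fold, and 13 rose and 0 fell by over 32-fold. The median change was 1.73 log2 units among the probes that rose and -1.53 among those that fell. Among the rises, 13 probes were well above background on all 4 BLM arrays and on no PBS array. Their approximate lower bounds on the fold ran from 3.07 to 44.1. In the other direction 5 probes were well above background only on PBS arrays, with approximate lower bounds on the fold of 1.52 to 5.51.

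**Figure D1:**
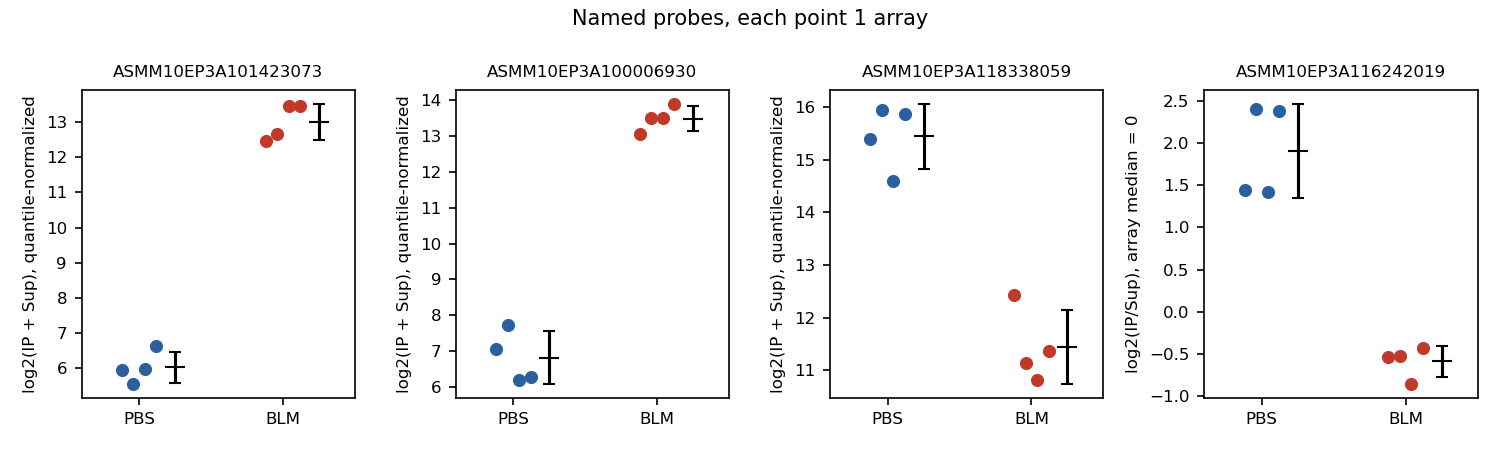
Signal of the 4 named probes on each array, with BLM and PBS points (n = 4 each) and bars showing mean ± SD. The first 3 panels plot quantile-normalized log2(IP + Sup) and the last plots log2(IP/Sup) with the array median set to 0. BLM and PBS points do not overlap in any panel, the last probe was well above background in IP on only 1 of 4 BLM arrays, and the first probe averages 13.01 in BLM and 6.02 in PBS.

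Of all tested probes, 7.63% had groups that did not overlap, where the average over all equal splits of the arrays is 2.86%. Single splits can lie far from that average, because probes move together. At an unadjusted p under 0.05 the labelled split had 7806 complete probes and the other splits had 179 to 22147. The share of 7.63% therefore does not exclude chance. The probe classes differed in the share called, with 2.17% of 44205 probes in the class ASMM10EP3A, 1.47% of 7266 in ASMM10EP3B and 0.836% of 3468 in ASMM10SM1, a difference between classes that was not tested. Scan and group overlap in these arrays. With scan as a block the difference comes only from the scan that held both groups, with 1 BLM array and 3 PBS arrays, so that fit is no separate check from the fit within that scan. With scan as a block limma called 66 probes (65 up, 1 down), of which 61 were among the 1095, and within that scan it called 0, with 3713 at an unadjusted p under 0.05. In that scan the differences were 7.40 and 6.77 log2 units for the 2 risen probes and -4.64 for the fallen one, with adjusted p of 0.17, 0.28 and 0.33. The count also depended on single arrays. It was 2381 (1186 up, 1195 down), 429, 520 and 528 without BLM replicate 1, 2, 3 or 4, and 594, 2849 (1370 up, 1479 down) and 554 without PBS replicate 2, 3 or 4.

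Gapdh, a glycolytic enzyme often used as a reference gene, had a higher sum of IP and Sup in BLM skin. Its 5′ control probe stood 3.51 ± 0.07 log2 units above the array's 75th percentile in BLM and 2.45 ± 0.12 in PBS (SD, n = 4 per group), a 2.08-fold rise (exact permutation p = 0.029, the smallest that 70 assignments can give, adjusted p = 0.049 over 12 comparisons). The 3′ probe of Gapdh rose 2.25-fold, from 4.11 ± 0.43 to 5.28 ± 0.08 (SD, n = 4 per group, same exact p). Pgk1, another glycolytic enzyme, rose 1.85-fold at its 3′ probe, from 3.82 ± 0.42 to 4.71 ± 0.11 (SD, n = 4 per group, same exact p). Every BLM array lay above every PBS array for these 3 probes. At the 5′ probe of Gapdh, Sup alone rose by 1.28 log2 units (limma adjusted p = 0.00080). IP alone differed there by 0.60 (limma adjusted p = 0.50). The 5′ probe of Pgk1, far dimmer and in part not well above background, differed by 0.48 log2 units (1.39-fold, exact permutation p = 0.14), and PBS replicate 1 lay above every BLM array there. Within the shared scan, BLM replicate 3 exceeded the mean of the 3 PBS arrays by 1.18, 1.46 and 1.12 log2 units for Gapdh 5′, Gapdh 3′ and Pgk1 3′. The direction was the same under the other scalings tried, but with candidate spike-in scaling only 1 of 4 BLM arrays stood above all PBS arrays for Pgk1, and without any scaling 2 of 4 for Pgk1 and 3 of 4 for Gapdh 3′. The 3′ over 5′ signal of Gapdh in Sup, a sign of RNA quality, also differed, at 1.84 ± 0.07 log2 units in BLM and 1.46 ± 0.24 in PBS (SD, n = 4 per group, exact permutation p = 0.029). In IP it was 1.60 ± 0.18 in BLM and 1.83 ± 0.57 in PBS (SD, n = 4 per group, exact permutation p = 0.51). That of Pgk1 is not used, as its 5′ probe lay partly at background.

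**Figure D2:**
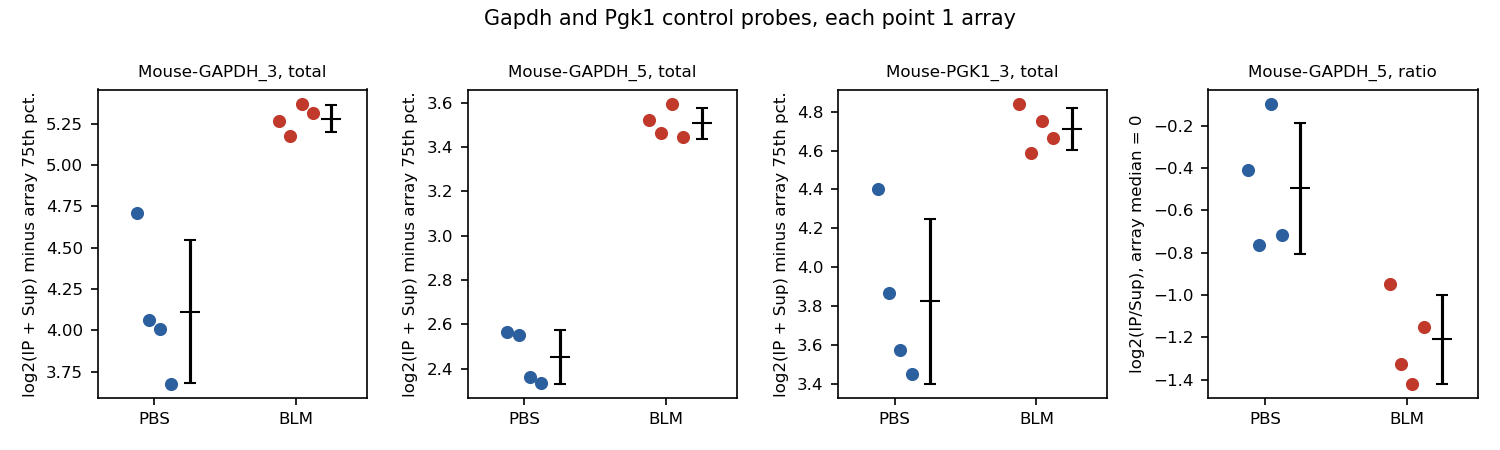
Gapdh and Pgk1 control probes on each array, BLM and PBS (n = 4 each), with bars showing mean ± SD. The first 3 panels plot log2(IP + Sup) minus the array's 75th percentile and the last plots log2(IP/Sup) with the array median set to 0. Gapdh 5′ averages 3.51 in BLM and 2.45 in PBS for the total, and -1.21 and -0.50 for the ratio.

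The m6A ratio, IP over Sup relative to the rest of the array, fell at 9 probes and rose at 0 in BLM skin, of 51236 tested by limma, with 3237 higher and 2548 lower at an unadjusted p under 0.05. At 8 of these probes both channels were well above background on all 8 arrays, with differences between -2.34 and -1.81 log2 units. At the other one, probe ASMM10EP3A116242019, log2(IP/Sup) was 1.91 ± 0.56 in PBS and -0.59 ± 0.19 in BLM (SD, n = 4 per group, difference -2.50, SE 0.30, limma adjusted p = 0.044). This probe was well above background on only 1 of 4 BLM arrays in IP and 2 of 4 in Sup, so its ratio in BLM rests mostly on signal near background, and with normexp the difference was -1.11 (limma adjusted p = 0.051). The IP signal fell at 8 of the 9 probes and rose at 1, while the Sup signal rose at 1 and fell at 1. The sum of IP and Sup, which stands for total abundance, fell at 7 of the 9 and rose at 1. IP is part of that sum, so these falls are not separate from the falls in IP. At probe ASMM10EP3A100065219 the sum fell by 1.11 log2 units while Sup differed by 0.019 (limma adjusted p = 0.97). Gapdh had a lower ratio in BLM, with -1.21 ± 0.21 against -0.50 ± 0.31 at its 5′ probe and -1.45 ± 0.39 against -0.13 ± 0.80 at its 3′ probe (SD, n = 4 per group, exact permutation p = 0.029 for both, adjusted p = 0.049). Unlike most of the 9 probes, its 5′ probe did not fall in IP, where it differed by 0.60 log2 units (SE 0.24, limma adjusted p = 0.50). In Sup it rose by 1.28 (limma adjusted p = 0.00080), so the lower ratio there came with the rise in Sup. The ratio difference of Gapdh kept its sign under the other scalings tried, although with the constants of the value table only 2 of 4 BLM arrays, and with candidate spike-in scaling 3 of 4, lay below all PBS arrays at either probe. For the Pgk1 3′ probe the ratio was -1.03 ± 0.53 in BLM and -0.41 ± 0.71 in PBS (SD, n = 4 per group, exact permutation p = 0.23).

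With scan as a block limma called 0 probes for the ratio, with 6378 at an unadjusted p under 0.05, and with scan as a random block it called 8, all among the 9. The difference of probe ASMM10EP3A116242019 was -2.92 (SE 0.50, adjusted p = 0.31) with scan as a block, where its SE was 0.30 without, so its call ended with the wider error and not with a smaller difference. The fit within the shared scan gave 0 calls and 4196 at an unadjusted p under 0.05. This fit and the one with scan as a block rest on 1 BLM array against 3 PBS arrays and say little about the 9. The count was 2, 0, 1 and 1 without BLM replicate 1, 2, 3 or 4 (3443 at an unadjusted p under 0.05 where it was 0), and 3 and 5 without PBS replicate 3 or 4. With the deposited value table, which is not centred, 1 probe rose and 0 fell, and with normexp background correction 48 rose and 38 fell.

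In the IP fraction alone, 189 probes rose and 28 fell of 53157 tested by limma, with 2136 higher and 1747 lower at an unadjusted p under 0.05. In the Sup fraction alone, 1322 rose and 1025 fell of 52211, but 4345 were higher and 5517 lower at an unadjusted p under 0.05. Of 51236 probes tested in both, 161 rose in both fractions, where independent lists would share 4.71, and 7 fell in both, where independent lists would share 0.531. No probe rose in one fraction and fell in the other. Both fractions come from the same RNA, so the overlap is not that of independent experiments. Probe ASMM10EP3A101423073 rose by 6.84 log2 units in IP (SE 0.34) and 7.12 in Sup (SE 0.33), and its ratio differed by -0.22 (SE 0.29, limma adjusted p = 0.80). In PBS it was well above background on 3 of 4 arrays in IP and 2 of 4 in Sup, so these values rest partly on signal near background. For probe ASMM10EP3A118338059 the Sup signal fell by 3.89 log2 units (SE 0.25, limma adjusted p = 0.00013) and the IP difference was -4.15 (SE 1.2, limma adjusted p = 0.36).

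With scan as a block, limma called 2 probes in IP and 67 in Sup, and within the shared scan 0 in each, with 4849 and 4257 at an unadjusted p under 0.05. For IP the count was 88, 106 and 107 without BLM replicate 2, 3 or 4 and 445, 98 and 104 without PBS replicate 1, 2 or 4, and for Sup it was 6606 (2757 up, 3849 down), 1148, 1233 and 1310 without BLM replicate 1, 2, 3 or 4 and 1505, 4408 and 1286 without PBS replicate 2, 3 or 4.

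The median log2(IP/Sup) over all tested probes, which asks for a shift common to all transcripts, was -0.00096 ± 0.0097 in BLM and -0.031 ± 0.021 in PBS (SD, n = 4 per group, exact permutation p = 0.029). The dye normalization of the processed signals sets every array's ratio near 0, so this difference of 0.030 cannot show a global change. On the scale of the deposited value table the medians were -0.69 ± 0.46 in BLM and -0.82 ± 0.19 in PBS (SD, n = 4 per group, exact permutation p = 0.66). With candidate spike-in scaling they were 0.14 ± 0.28 and 0.14 ± 0.12 (SD, n = 4 per group, exact permutation p = 0.97). Some probes with the spike-in-like name varied widely within groups in Sup, so this scaling cannot settle whether the ratio shifted.

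**Figure D3:**
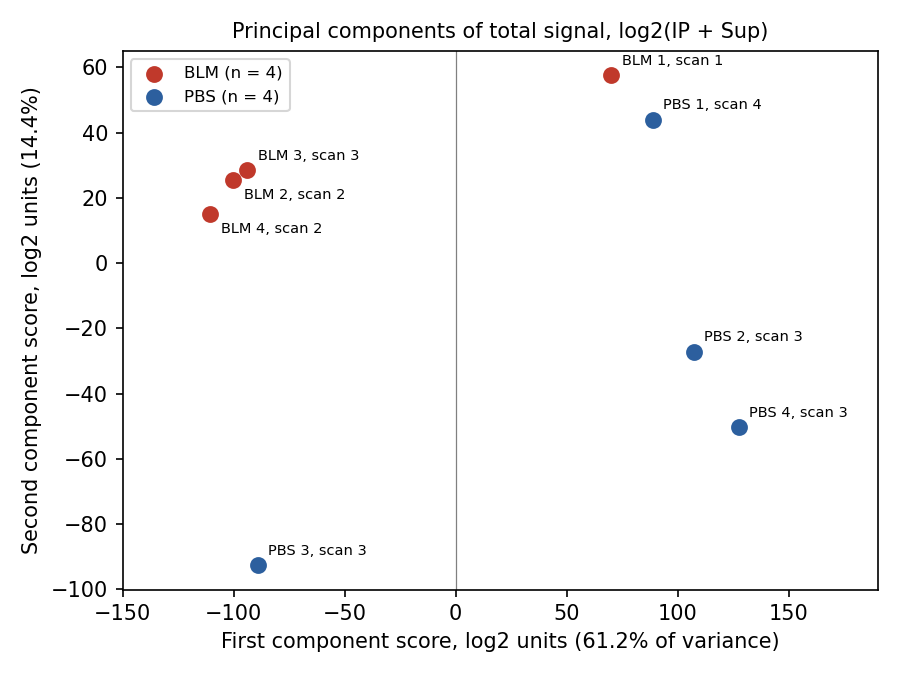
First and second principal component of log2(IP + Sup), in log2 units, with 1 point per array coloured by group and named by replicate and scan. The first component holds 61.2% of the variance and sets BLM replicate 1 at 70.1 beside 3 PBS arrays, and PBS replicate 3 at -89.1 beside 3 BLM arrays.

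The arrays did not part by group on the first principal component of expression, which held 61.2% of the variance. BLM replicates 2, 3 and 4 scored between -110.4 and -94.0 and BLM replicate 1 scored 70.1, while PBS replicates 1, 2 and 4 scored between 88.7 and 127.5 and PBS replicate 3 scored -89.1. Without these 2 arrays, a choice made after seeing the data that leaves 3 arrays per group parted by this component, limma called 17411 probes for expression (8740 up, 8671 down), 4546 for IP (2186 up, 2360 down), 21098 for Sup (10375 up, 10723 down) and 225 for the m6A ratio (174 up, 51 down). The balance of rises and falls in the 4 comparisons therefore depends on the arrays and the threshold used.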

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

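All tests in this part were chosen after the data were seen, except the test of scans on the probes higher in BLM and the test of slopes, whose outcomes were not known when they were set. Of 64 groups of 4 arrays examined, 6 had an array far from the other 3, where chance gives about 3.2.

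BLM replicate 1 stood apart from the other BLM arrays on the first component of expression (70.1) and of the IP signal (58.2), and PBS replicate 3 stood apart from the other PBS arrays on that of the Sup signal (-92.7). An exchange of the labels of these 2 arrays would make the labelled split no better than 15 others. Those 15 also exchange 1 array of each side of the component. The labelled split called 1098 probes over 54823 complete probes and those 15 called 0 at most. At an unadjusted p under 0.05, however, the labelled split had 7806 probes and a split among those 15 had 8071. First place among 16 splits also cannot reach a share under 0.05. The adjusted calls of these 16 splits therefore go against an exchange without excluding it. With the 2 labels exchanged, the split is that of the first component, which called 15175 probes. BLM replicate 1 correlated at 0.965 to 0.970 with PBS replicates 1, 2 and 4, and at 0.937 to 0.942 with the other BLM arrays. PBS replicate 3 correlated at 0.963 to 0.973 with BLM replicates 2, 3 and 4, and at 0.914 to 0.920 with the other PBS arrays. Such values would also follow from an exchange, so it stays open. The first component spanned 221 log2 units among the 4 arrays of the shared scan, more than the 117 between the group means. For PBS replicate 3 a difference between scans is argued against, since it scored -89.1 while PBS replicates 2 and 4 of the same scan scored 107.4 and 127.5. BLM replicate 1 was the only array of its scan, so for it a difference between scans cannot be told apart. Its Sup channel was read at a scanner detector voltage of 332, where the other arrays had 353 or 354. In IP its voltage was 407, within the 391 to 418 of the other arrays. An effect of the voltage was not tested. RNA integrity as read from Gapdh 3′ over 5′ in Sup goes the other way, with PBS replicate 3 at 1.21 log2 units, farther from the BLM mean of 1.84 than the PBS mean of 1.46. In Sup some control probes outside the array design parted the arrays on the same sides. Probe (+)E1A_r60_a22 read 8.17 log2 units in BLM replicate 1 and 10.08 to 10.96 in the other BLM arrays. It read 10.13 in PBS replicate 3 and 8.10 to 8.58 in the other PBS arrays. Probe ASSPINKEIN100003643 took the opposite direction, and other control probes did not part this way. A technical source is therefore not excluded. What sets the component stays open, and no biological explanation was tested, since the labels give no further property of the mice.

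The same structure limits what counts of calls can show about chance. Of the 35 splits of the 8 arrays into 4 and 4, 2 called as many probes as the labelled one for expression (1098 against 15175 for the other), 2 for IP (217 against 5213), 2 for Sup (2351 against 16154) and 3 for the m6A ratio (9 against at most 1216). Chance is therefore not excluded by the number of calls for any of the 4. The higher count for expression, IP and Sup came from the split of the first component, which is the labelled split with BLM replicate 1 and PBS replicate 3 exchanged. It was several times the labelled count, which points to a structure of the arrays whose source stays open.

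Scan differences were tested as a source of the higher expression in BLM, because only 1 scan held both groups. On the arrays of the other scans, 52 probes had BLM replicates 1, 2 and 4 all over 8-fold above PBS replicate 1. Within the shared scan, BLM replicate 3 exceeded PBS replicate 3, which shares its side of the first component, by a median of 4.18 log2 units at these probes (quartiles 2.93 and 5.58), against 0.0042 over all probes. BLM replicate 3 lay above all 3 PBS arrays at 52 of the 52. The check was weaker for falls, where 18 probes picked in the same way differed by a median of -1.78 log2 units, and BLM replicate 3 lay below all 3 PBS arrays at 14 of the 18. The probes were picked and checked on separate arrays of the series. The values argue against scans as the source of those rises, and a response to bleomycin remains a hypothesis.

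The IP/Sup ratio moved against expression. Over 51121 probes the slope of the ratio change on the expression change was -0.34. Ratio and expression come from the same IP and Sup signals, so a change or noise in either channel moves both. Among 601 probes that rose in expression 75.9% had a lower ratio in BLM, against 15.2% among 422 that fell and 50.6% of all probes. The probes that rose or fell were picked on the sum of those same signals, so these shares are no separate evidence. Of the 35 splits, 7 gave a slope as far from 0, and the other splits ranged from -0.42 to 0.43, so differences between arrays unrelated to the label could account for the slope.

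Among other results, PBS replicate 3 had a median log2(IP/Sup) over all design probes of -0.090, where the other PBS arrays lay between -0.0044 and 0.0094. PBS replicate 1 had 92.9% of probes well above background in IP, where the other PBS arrays had 85.5% to 86.6%. The Pgk1 5′ control probe of PBS replicate 1 stood at -3.36 log2 units from the 75th percentile, where the others lay between -4.63 and -4.54. Among 170 control and replicated probes outside the array design that were tested in Sup, leaving out the mouse Gapdh and Pgk1 probes, 20 were higher in BLM than in PBS and 6 lower by limma, but 6 of the 20 are probes for human or rat Gapdh and Pgk1 and are not independent of the mouse probes, and of 169 in IP 0 were higher and 4 lower.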

How the results depend on the processing

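The tests within the shared scan, with scan as a random block, without both BLM replicate 1 and PBS replicate 3 and on signals without dye normalization, and those of the median ratio on the value table, on candidate spike-in scaling and without dye normalization, were chosen after the data were seen. Main counts were 9 for the m6A ratio, 1095 for expression, 217 for IP and 2347 for Sup. In that order, the counts became 4, 535, 119 and 1133 with candidate spike-in scaling, 5139, 23569, 16396 and 24863 with array weights, 4604, 5842, 3201 and 8471 at an unadjusted p under 0.05 and 1.5-fold, 0, 66, 2 and 67 with scan as a block, 0 in each within the shared scan, and 225, 17411, 4546 and 21098 without both arrays. The fall within the shared scan comes with 4 arrays and a lone BLM array assumed to vary like PBS. Other thresholds change the counts by construction, and the causes of the other moves were not tested. With treat at 1.2-fold expression fell to 689 and Sup to 1449, with the value table Sup fell to 1451 and the ratio to 1, and without dye normalization expression fell to 726. The ratio gave 86 calls with normexp, 3 with quantile normalization of log ratios and 14 on the log-odds of the methylated share. With array weights 2979 of the ratio calls were up and 2160 down, of expression 11732 and 11837, of IP 8041 and 8355, and of Sup 11740 and 13123. At an unadjusted p under 0.05 and 1.5-fold they were 2501 and 2103 of the ratio, 2936 and 2906 of expression and 3828 and 4643 of Sup. Leaving out 1 array gave 0 to 7 calls for the ratio, 429 to 2849 for expression, 88 to 445 for IP and 1148 to 6606 for Sup. Apart from the replicate block, the other alternatives stayed within 1.5 times the main count, among them 943 for expression and 8 for the ratio with scan as a random block. Of the IP calls with candidate spike-in scaling 88 rose and 31 fell, against 189 and 28. The median BLM minus PBS over tested probes was -0.011 log2 units for expression, -0.0033 for IP, -0.021 for Sup and -0.0049 for the ratio. On the value table it was -0.11 for expression, -0.16 for Sup and 0.13 for the ratio, and with candidate spike-in scaling -0.15 for expression, -0.14 for IP and -0.15 for Sup.

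With replicate number as a replicate block the counts were 0 (4766 at an unadjusted p under 0.05), 508, 46 and 1297, and the median ratio difference was 0.030 with an exact permutation p of 0.13, the smallest that 4 differences allow. The numbers gave no clear sign of a pairing of the arrays. Deviations of same-numbered arrays correlated across probes between -0.57 and 0.36 for expression and between -0.33 and -0.037 for the ratio, and most arrays correlated better with another number. BLM replicate 1 and PBS replicate 3, which stand apart in their groups, weigh on these deviations, so a weaker pairing is not excluded. The median ratio difference of 0.030 turned to -0.025 at the 75th percentile and lost its call with 0.0018 over all design probes, 0.0074 with candidate spike-in scaling, 0.14 on the value table and 0.019 without dye normalization, with exact permutation p between 0.34 and 1. Leaving out 1 array gave 0.019 to 0.035, and 5 of these 8 tests lost the call, with exact permutation p of 0.057 to 0.086. The cause was not tested. Probes ASMM10EP3A101423073, ASMM10EP3A100006930 and ASMM10EP3A118338059 kept their direction under all 23 alternatives and their call under 22, 21 and 21. All 3 lost the call within the shared scan. The last 2 also lost it with scan as a block, with differences of 6.77 and -4.64 log2 units. With normexp the differences of the first 2 shrank to 4.10 and 4.47 log2 units, in the opposite order. Probe ASMM10EP3A116242019 kept its direction under 24 and its call under 7, with adjusted p from 0.0016 to 0.60, and with normexp its difference shrank from -2.50 to -1.11 (adjusted p = 0.051). Gene list tests were not run, as probes carried no gene names. Signal over background limits what Sup can show on BLM replicate 2, where 69.6% of probes were well above background.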

Other observations

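Control probes outside the array design held a difference in the IP channel. The control probes DCP_20_7 and DCP_20_9 were lower in BLM, with log2 differences from PBS of -2.99 (SE 0.41) and -2.60 (SE 0.34), all 4 BLM arrays below all 4 PBS arrays and limma adjusted p of 0.0017 and 0.0016. They were the only 2 called of 12 probes with DCP names tested in IP. In Sup 0 of 11 such probes were called, and DCP_20_7 and DCP_20_9 had limma adjusted p of 0.48 and 0.44. Among the probes with a spike-in-like name, 2 of 72 tested in IP were lower in BLM and 0 of 75 in Sup differed by limma.

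BLM replicate 1 lay over 8-fold below the other 3 BLM arrays at 178 probes, and PBS replicate 3 lay over 8-fold above the other 3 PBS arrays at 548. At 165 probes both held. In the opposite direction, BLM replicate 1 lay over 8-fold above the other BLM arrays at 151 probes, PBS replicate 3 lay over 8-fold below the other PBS arrays at 134, and both held at 42. All 4 BLM arrays lay over 8-fold above all 4 PBS arrays at 27 probes, and at 0 the other way.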
